A study of Homo sapiens with 2 samples.

How the data were processed

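Gene expression was measured in Y79, a human retinoblastoma cell line that grows in suspension, after infection with lentiviral particles that encode the trefoil peptide TFF1 or with control particles. Total RNA of the infected cells was hybridised to 2 two-colour Agilent arrays, and the labels describe the arrays as biological replicates. On both arrays the RNA of the TFF1-overexpressing cells carried Cy5, read in the red channel, and the control RNA carried Cy3, read in the green channel, per the labels. No array had the dyes the other way round, so a dye effect that is specific to a probe cannot be separated from an effect of TFF1 in any ratio given here. The file headers place both arrays on a single slide and in a single scan, so there was no slide or scan batch to test.

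The scanner files were made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. They hold the mean signal and the median local background of each spot as intensity on a linear scale, without normalization, per the file headers. The processed signals in the deposited files are intensities that the scanner software had background-subtracted, detrended and dye-normalized by linear scaling and LOWESS, with surrogates at dim spots. The deposited log ratio of each spot is the log10 of red over green processed signal, and the deposited p-value of that ratio comes from the software's error model within a single array. The deposited value table of the series holds log2 ratios. Its scale, direction and centring were found by comparison with the scanner files: the slope on the log2 ratio of the processed signals was 1.00 on array 1 and 1.00 on array 2, and the median was -0.059 on both. What else was done to make that table is not given in the sources used here.

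Each array had 44495 spots, of which 43118 were not controls and represented 34127 probes. The median signal over non-control spots was 133 in green and 227 in red on array 1, and 145 in green and 236 in red on array 2. The median background was 36 and 38 in green and 64 and 65 in red. On array 1, 61.8% of the probes were well above background in green and 71.6% in red. On array 2 these shares were 63.7% and 72.9%. No spot was saturated (0 on each array). The software's fit of observed on expected log ratios of the spike-in probes had a slope of 0.880 on array 1 and 0.853 on array 2. The intercepts were 0.23 and 0.50 on the log2 scale, and the correlations were 0.986 and 0.986. The number of arrays limits the precision.

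Background was corrected with normexp at an offset of 50, from the mean signal and the median background of each channel. Ratios of red over green were then normalized within each array by loess, with control spots at weight 0, and spots of the same probe were averaged. Spots that the software marked as non-uniform, in the spot or in its background and in either channel, were left out before normexp. They were 67 spots on array 1 (26 for the spot and 58 for its background) and 2 on array 2. This order departs from the plan set before the data were examined, in which those spots were left out after normexp. The change was made after the data had been seen. By then the counts of calls under several other settings, run with the planned order, had also been seen, but not those of the new order. The reason was the background fit on array 1. With all spots, among them one with a net green signal of -38960, the fitted background mean was -481 in green and -246 in red. With the marked spots left out first it was 11.5 and -5.12. On array 2 it was 8.64 in green and -6.91 in red under either order. Results of the planned order are given beside the counts in the report and in the closing section.

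Probes were tested if they were well above background on both arrays in the same channel, which 24023 probes were (70.4%). The log2 ratio of TFF1-overexpressing over control cells was tested against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes). P-values were adjusted by the Benjamini-Hochberg method, and a probe was called at an adjusted p under 0.05. With 2 arrays the fit had 1 residual degree of freedom, to which the spread shared over probes added 10.7, so that the test of each probe relies on the spread of all probes. A gene was called if a probe of it was called and no other called probe of it went the other way. For the value of a gene and for gene lists, the brightest tested probe stood for the gene. Gene names are those of the array design. Of the probes, 26246 (76.9%) were matched by accession to a RefSeq table of GRCh38.p14, which was used for names only, and 2248 of these had another symbol there. Coordinates are those of the scanner files, on hg19. For a probe that was not well above background in a channel on both arrays, a fold is given as a bound, computed per channel after loess and Aquantile normalization and open to dye bias.

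Gene lists, 37 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists. All 37 had at least 5 tested genes. Camera with an estimated correlation and fry were run beside it. Counts of members are given over all tested probes and, where so named, adjusted over the list alone, which uses the brightest probe of each member. The rule for naming genes, set before the data were examined, took TFF1, then the 12 genes with the highest and the 12 with the lowest mean log2 ratio among called genes with the same direction on both arrays. Symbols that are only an accession, a clone or an uncharacterised reading frame were left out of these. The rule also took up to 4 members of each list described and 13 genes chosen beforehand for the question of the study or the cell type. Which lists to describe by their members, 21 of the 37, was decided after the list results and the effect of the settings had been seen. Genes named outside the rule are said to be so where they appear, and a few genes that the rule takes are not reported here.

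The procedure was tested on simulated data, in which 200 of the 24023 tested probes were given a known log2 ratio at the noise of the real arrays. Of 50 probes at each size, 50 were called at a ratio of -1, 49 at -0.5, 50 at 0.5 and 50 at 1, and 12 of the 23823 unchanged probes were called. The simulated ratio of 1 came back at a median of 0.88 on array 1 and 0.87 on array 2, since the offset draws the ratios of dim probes towards 0. With the planned order it came back at 0.35 and 0.87, and 17 of the 50 such probes were called. The simulation held no dye effect, and the noise of all its spots came from the same spread (SD 0.10 on the log2 scale). Its changed probes were at 0.5 or 1 in size, while the called ratios of the real arrays had a median size of 0.29. It therefore does not show how well ratios of that size are called.

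The alternatives were no background correction, the processed signals of the scanner software, median centring in place of loess, the value table, no filter and a stricter filter on dim probes, eBayes with an intensity trend and robust settings, a minimum fold, the channels as separate samples, other list tests and each replicate left out. Removal of the trend on base composition and the planned order of background correction were added after the data had been seen. Figures were drawn from the tables of results.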

Results

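The comparison was of Y79 retinoblastoma cells infected with TFF1-coding lentivirus against Y79 cells infected with control particles, on 2 arrays of paired RNA. The title of the series relates TFF1 overexpression to p53 and caspase signalling and to miR-18a, and the groups of genes were chosen with that question in mind. Each array gave a ratio of TFF1-overexpressing over control RNA for 34127 probes, of which 24023 were bright enough to be tested. On array 1, 21081 probes were well above background in the control channel and 24443 in the TFF1 channel. On array 2 these numbers were 21727 and 24885. All values below are log2 ratios of TFF1-overexpressing over control cells, as the mean of 2 arrays with the standard error of the limma fit, unless said otherwise. The TFF1 RNA was in Cy5 on both arrays, so each ratio holds the effect of the lentivirus together with any effect of the dye on that probe. It also holds any other difference between the cultures.

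TFF1, a small secreted trefoil peptide of mucosal epithelia, had the highest ratio of all tested probes. Its level was 3.08-fold higher in the TFF1-overexpressing cells (log2 1.62 ± 0.13, SE, n = 2; SD 0.53; limma adjusted p 0.000406). The ratio was 1.25 on array 1 (2.38-fold) and 1.99 on array 2 (3.98-fold). The control signal was 221 on array 1 and 214 on array 2, over a background of 37.5 on each, and the signal of the TFF1-overexpressing cells was 1040 and 1574, over 72 and 67. The only probe of the gene, A_24_P322771, lies on the minus strand of chromosome 21 at 43783440 to 43783499 (hg19) and starts at position 142 of its target transcript. Its 60 bases, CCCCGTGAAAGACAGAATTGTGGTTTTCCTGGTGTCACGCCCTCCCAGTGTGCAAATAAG, lie in the coding sequence, so the probe does not tell the cell's own transcript from that of the virus. The processed signals of the scanner software gave 1.46 and 2.34, with a mean of 1.90 that did not pass the threshold (adjusted p 0.14). TFF2 and TFF3, the other members of the trefoil family, were at 0.11 ± 0.08 and 0.23 ± 0.07 (adjusted p 0.37 and 0.064). The control channel was well above background on 1 array for TFF2 and on 0 for TFF3, where the bound was at least 1.17-fold higher. Under median centring both TFF2 and TFF3 had ratios below 0, at -0.17 and -0.095. That setting leaves the trend of ratio with brightness in place.

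Beyond TFF1, many small differences passed the test: 2547 probes were called, 1380 higher and 1167 lower in the TFF1-overexpressing cells. Each had the same direction on both arrays. With 2 arrays the test can hardly call a probe with opposite signs, so that agreement was nearly fixed by the test and is no evidence of replication. By gene, 1302 were higher, 1093 were lower and 13 had called probes in both directions, of 18439 gene names tested. The counts of called list members given below are to be read beside these and were not tested against them. A list of any genes would hold some calls. The median size of the called ratios was 0.29 (1.23-fold) and their 95th percentile was 0.46 (1.37-fold). TFF1 was the only called probe with a mean ratio of at least 1 on the log2 scale. Over the tested probes the ratios of the arrays correlated with Pearson's r of 0.56 and Spearman's rho of 0.55, across probes, which are not independent replicates. When the sign of array 2 was turned, 1 probe was called, that of ID1. All that the arrays share, a common dye effect included, then counts as spread. The turned count therefore describes differences between the replicates and gives neither a p-value nor a rate of false calls. The count of calls depended on the processing. With the order of background correction planned before the data were examined, 1539 probes were called, 1117 higher and 422 lower, and 1142 of them were shared. Median centring in place of loess called 17600 probes, 12517 higher and 5083 lower, and left a median of -0.29 over the dimmest 25% of probes and 0.46 over the brightest 25%. A change of sign under median centring, as given for genes and lists in this report, can therefore follow from brightness alone. The processed signals of the scanner software, tested with limma, called 0 probes, with 5309 at an unadjusted p under 0.05 against 7055 in the fit reported here.

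**Figure D1:**
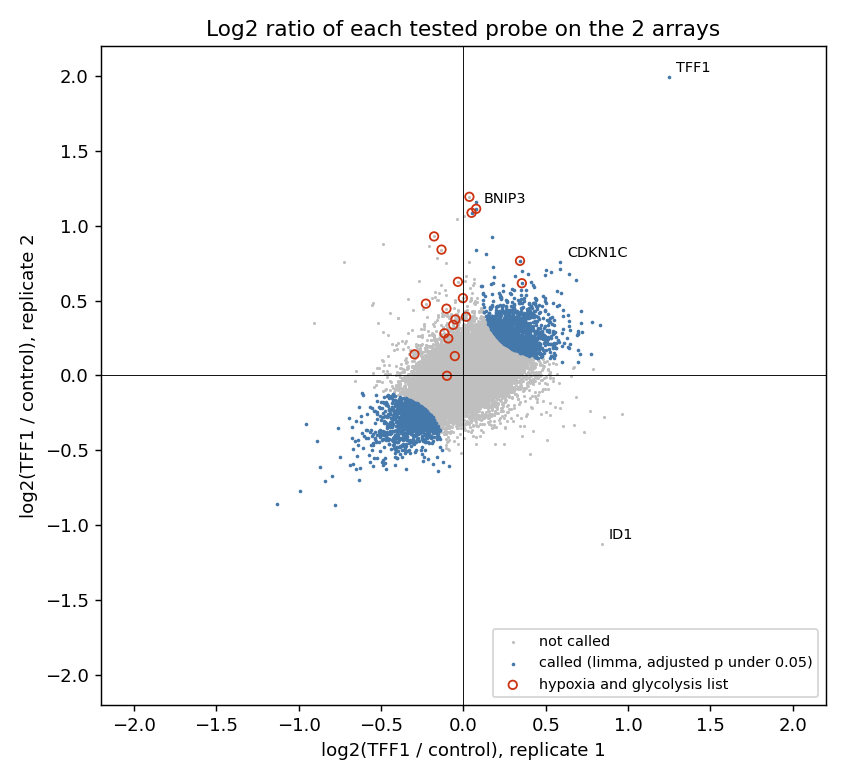
Log2 ratio of TFF1-overexpressing over control cells for each of the 24023 tested probes, on the array of replicate 1 (horizontal axis) and of replicate 2 (vertical axis), with the 2547 called probes in blue, the others in grey and the 19 tested genes of the hypoxia and glycolysis list circled. TFF1 stands apart at 1.25 and 1.99, ID1 has opposite signs at 0.84 and -1.13, and most circled genes lie near 0 on array 1 and above 0 on array 2.

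After TFF1, the highest called gene was CDKN1C, which encodes the cyclin-dependent kinase inhibitor p57. It was 1.59-fold higher (0.67 ± 0.07, adjusted p 0.00143), with 0.59 on array 1 and 0.76 on array 2. GIPR, the receptor for glucose-dependent insulinotropic polypeptide, rose by 0.65 ± 0.07, and the histone gene HIST1H2AC by 0.58 ± 0.10, with 0.83 on array 1 and 0.34 on array 2. Other probes of HIST1H2AC were at 0.29, which was called, and at 0.03. RPS2 and RPL13A, which encode ribosomal proteins, rose by 0.66 ± 0.07 and 0.58 ± 0.07. Other probes of RPS2 were at 0.47, which was called, and at 0.08, which was not, and those of RPL13A at 0.46 and 0.39, both called. The RPL13A probe at 0.46 is placed on chromosome 10 and those at 0.58 and 0.39 on chromosome 19, so it may not read RPL13A alone. The TPT1 pseudogene TPT1P8 had a ratio of 0.57 on array 1 and 0.56 on array 2, which a probe of a pseudogene can share with its parent gene. The vasodilator peptide gene ADM rose by 0.56 ± 0.09, with 0.34 on array 1 and 0.77 on array 2. RAB17, BNIP3 and PFKFB4 were also among the highest, at 0.62 ± 0.17, 0.60 ± 0.17 and 0.57 ± 0.17, but these means came from array 2. On array 1 they were at 0.08, 0.08 and 0.05, and on array 2 at 1.16, 1.11 and 1.09 (adjusted p 0.0418, 0.0418 and 0.0493). The other probe of RAB17 was at 0.16 and not called.

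The lowest called genes were NPIPB3, a member of the nuclear pore complex interacting protein family, at -0.88 ± 0.07 (adjusted p 0.000436), and the non-coding transcript LINC00597 at -0.82 ± 0.07 (adjusted p 0.000436). NPIPB3 was not well above background in the TFF1 channel on either array, so it was at least 1.72-fold lower, and its probe can share signal with near-identical family members. ORM1, which encodes the acute phase protein orosomucoid, was 1.71-fold lower (-0.77 ± 0.07). GDAP1, a mitochondrial protein gene mutated in a hereditary neuropathy, was 1.56-fold lower (-0.64 ± 0.07), as was FXR2, a paralogue of the fragile X protein (-0.64 ± 0.07). EID3 was at -0.64 ± 0.11, with -0.95 on array 1 and -0.32 on array 2. The transcription factor gene KLF17 was at -0.57 ± 0.07, the spliceosome component SNRNP70 at -0.55 ± 0.07, the pseudogene AFG3L1P at -0.54 ± 0.07 and FRMD4A at -0.53 ± 0.07. The intronic transcripts KCNQ5-IT1 and ASAP1-IT1 were at -0.67 ± 0.07 and -0.56 ± 0.09, and ASAP1-IT1 was at -0.76 on array 1 and -0.35 on array 2. Other probes of AFG3L1P were at -0.22 and 0.04 and of FRMD4A at -0.18 and -0.03, none of them called.

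Genes of the p53 response went both ways. Of 25 measured p53 targets, 2 rose, 3 fell and 20 did not pass the test, and 4 rose and 2 fell when adjusted over the list alone. TIGAR (C12orf5 on the array), a regulator of glycolysis, rose by 0.26 ± 0.07, and the death receptor TNFRSF10B by 0.24 ± 0.07. PHLDA3, an inhibitor of AKT, and the kinase PLK3 fell by 0.25 each, but were at 0.16 and 0.16 under median centring. PHLDA3 was at -0.14 on array 1 and -0.36 on array 2. AEN, a nuclease named after its values were seen, was the other gene lower, through a probe at -0.48 with its brightest probe at -0.12. CDKN1A, which encodes the cell cycle inhibitor p21, was at -0.13 ± 0.10 (adjusted p 0.41), with 0.12 on array 1 and -0.38 on array 2. MDM2, the ubiquitin ligase that acts on p53, was at 0.17 ± 0.07 (adjusted p 0.12). As a list, p53 targets did not pass camera (mean 0.051, adjusted p 0.60), and their mean was 0.13 on array 1 and -0.032 on array 2.

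Caspases and pro-apoptotic genes were likewise mixed, with 3 of 24 higher, 3 lower and 18 not called (2 and 2 adjusted over the list alone; camera adjusted p 0.99). The BH3-only gene BIK rose by 0.33 ± 0.08, with 0.48 on array 1 and 0.17 on array 2. DIABLO, an antagonist of the inhibitor of apoptosis proteins, fell by 0.31 ± 0.07 and APAF1, the scaffold of the apoptosome, by 0.24 ± 0.07. DIABLO had a ratio of 0.34 under median centring, and its other probe was at -0.04 and not called. The probes of CYCS, the cytochrome c gene, named after its values were seen, disagreed, at -0.17 for the brightest, 0.25 for the called probe and 0.17 for the other. CASP9 was at 0.15 ± 0.07 (adjusted p 0.15), and 0 of the 2 probes of CASP8 were bright enough to be tested. Among 13 anti-apoptotic genes, 1 rose and 2 fell (1 and 1 adjusted over the list alone). BCL2 rose by 0.31 ± 0.07 (adjusted p 0.0186), with its other probe at 0.06. BCL2L1 fell by 0.25 ± 0.07, and TRAF2 was lower through a probe at -0.27. Under median centring the brightest probes of BCL2L1 and TRAF2 were at 0.08 and 0.34. The list had a mean of -0.081 (adjusted p 0.12), which was 0.33 under median centring.

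Cell cycle genes were called in both directions. Of 24 genes of G2/M and mitosis, 0 rose and 4 fell (0 and 3 adjusted over the list alone). The mitotic kinase AURKB fell by 0.28 ± 0.07, KIF23 by 0.26 ± 0.07 and CDK1 by 0.23 ± 0.07, and PLK1 was lower through a probe at -0.32 with its brightest at -0.12. All of these had ratios above 0 under median centring, which does not take out the trend of ratio with brightness. AURKB was at -0.38 on array 1 and -0.17 on array 2, and the other probe of KIF23 was at -0.05 and not called. The list's mean was -0.068 (camera adjusted p 0.077), and 0.36 under median centring. The proliferation marker MKI67 was not called with any of its 3 probes (0.08, -0.11 and -0.05). Among 26 genes of G1/S and DNA replication, 1 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p 0.77). Thymidylate synthase, TYMS, rose by 0.44 ± 0.09, with 0.63 on array 1 and 0.25 on array 2. Thymidine kinase TK1 fell by 0.27 ± 0.07 and E2F1 by 0.26 ± 0.07, and the helicase subunit MCM7 was lower through a probe at -0.30. TK1, E2F1 and the brightest probe of MCM7 were at 0.36, 0.16 and 0.60 under median centring. CDKN1C was the only called gene of 9 CDK inhibitors and RB family members (2 and 0 adjusted over the list alone; camera adjusted p 0.65). MYCN, an oncogene amplified in this line, was at 0.24 ± 0.08 (adjusted p 0.064), with 0.11 and 0.37 on the arrays.

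The arrays measured messenger RNA and host transcripts, so miR-18a itself was not analysed here. MIR17HG, the host transcript of the cluster that encodes miR-18a, was at -0.072 ± 0.07 (adjusted p 0.56), with -0.18 on array 1 and 0.034 on array 2 and a ratio of 0.033 under median centring. Of 14 genes described as miR-18a targets, 1 rose, 2 fell and 11 were not called (1 and 1 adjusted over the list alone; camera adjusted p 0.77). The netrin receptor gene NEO1 fell by 0.33 ± 0.07. The nuclear receptor coactivator NCOA3 rose by 0.30 ± 0.07, with the control channel well above background on 1 array, and was at -0.018 under median centring. HIF1A was lower through a probe at -0.34, while its brightest probe was at 0.17 and not called. Of 10 microRNA host and processing genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p 0.60). DICER1 was at -0.15, AGO1 at 0.14 with its other probe at -0.10, DGCR8 at -0.11 and DROSHA at -0.098, with DICER1, DGCR8 and DROSHA above 0 under median centring.

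The hypoxia and glycolysis list was the only one of 37 that passed camera, with a mean of 0.26 over 19 measured genes (adjusted p 0.0374). The call was lost with an estimated correlation (adjusted p 0.92). That estimate rests on 1 residual degree of freedom and was 1 for this list. None of the 37 lists had an adjusted p below 0.92 in that test, so the loss says little about this list. Fry gave the list an adjusted p of 0.78. All 19 members had a higher ratio on array 2 than on array 1, so they moved together between the replicates. The preset correlation of 0.01 may therefore be too low for this list and its camera p too small. The call in the reported fit rested on array 2: the list's mean was -0.030 on array 1 and 0.55 on array 2. Of its members 4 rose and 1 fell (5 and 0 adjusted over the list alone). BNIP3, a mitophagy receptor, and PFKFB4, an enzyme that regulates glycolysis, rose with the values given above. ADM rose as well, and the histone demethylase KDM3A rose by 0.49 ± 0.08 with 0.36 and 0.62. BNIP3L, named after its values were seen, was lower through a probe at -0.27 while its other probes were at 0.14 and 0.09 and not called. Among 13 genes of oxidative stress and metallothioneins, MT1A rose by 0.43 ± 0.07, while thioredoxin reductase TXNRD1 fell by 0.42 ± 0.07 and GCLM, a subunit of the enzyme that starts glutathione synthesis, by 0.30 ± 0.07 (3 and 2 adjusted over the list alone; camera adjusted p 0.89). GCLM was at 0.24 under median centring.

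**Figure D2:**
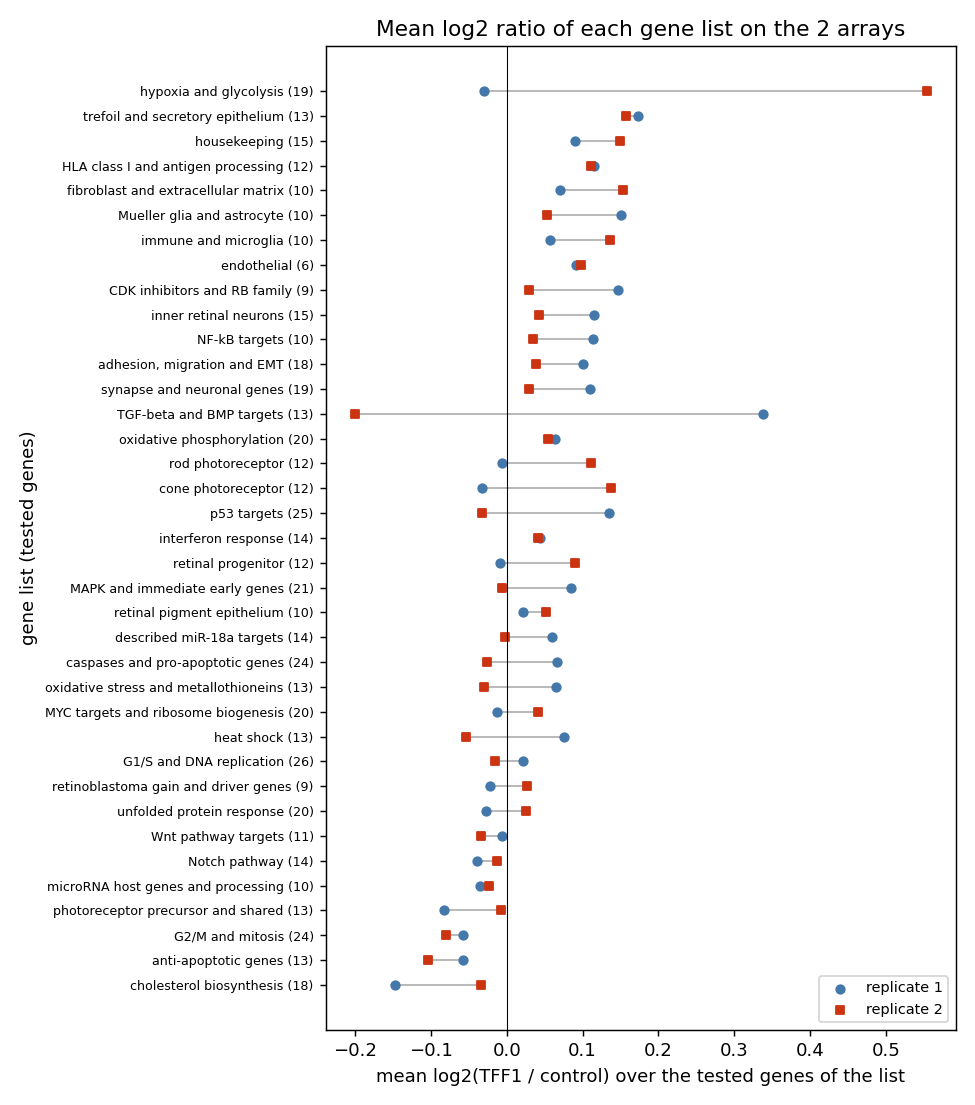
Mean log2 ratio of TFF1-overexpressing over control cells over the tested genes of each of the 37 lists (number in brackets), on replicate 1 (blue circles) and replicate 2 (red squares), with a grey line joining them. The hypoxia and glycolysis list lies at -0.030 and 0.55 and the list of TGF-beta and BMP targets at 0.34 and -0.20. Under median centring in place of loess, which leaves the trend of ratio with brightness in place, 9 of the list means change sign.

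Photoreceptor genes, which retinoblastoma lines of this kind express, gave 1 call in each of the cone and rod lists. Of 12 cone genes 1 rose, the opsin OPN1MW by 0.24 ± 0.07 (0 and 0 adjusted over the list alone), and of 12 rod genes 1 rose, the phosphodiesterase PDE6A by 0.32 ± 0.07 (1 and 0 adjusted over the list alone). Neither list passed camera (adjusted p 0.65 each). Among 13 genes of photoreceptor precursors, NEUROD1 rose by 0.24 ± 0.07 and PRDM1 fell by 0.31 ± 0.08 (1 and 1 adjusted over the list alone; camera adjusted p 0.56), and PRDM1 was at 0.09 under median centring. PRDM1 was at -0.43 on array 1 and -0.18 on array 2, and its other probe was at -0.07 and not called. CRX, the photoreceptor transcription factor, was at -0.16 ± 0.07 (adjusted p 0.14) and at 0.40 under median centring. Of 19 synaptic and neuronal genes, 3 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p 0.58). The neurofilament genes NEFL and NEFM rose by 0.41 ± 0.07 and 0.29 ± 0.08 (NEFM 0.42 on array 1 and 0.17 on array 2), and SNAP25, named after its values were seen, by 0.25. The synaptic vesicle genes VAMP2 and SYP fell by 0.33 ± 0.07 and 0.27 ± 0.07, with ratios of 0.0067 and 0.06 under median centring. The other probes of VAMP2 were above 0 at 0.07 and 0.05 and not called.

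Genes of antigen presentation and markers of other cell types were measured as well. Of 12 genes of HLA class I and antigen processing, 3 rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p 0.15). The peptide loading factor TAPBP rose by 0.33 ± 0.08 and HLA-G by 0.27 ± 0.07, and HLA-C was higher through a probe at 0.34, with its brightest at 0.17. TAPBP was at 0.47 on array 1 and 0.18 on array 2, and its other probes were at 0.12 and 0.03 and not called. Probes of HLA genes can share signal with their paralogues. Among markers of other cell types, 1 of 6 endothelial genes rose (VWF, by 0.43 ± 0.07), 2 of 10 fibroblast and matrix genes rose (THBS1 by 0.29 ± 0.07 and SPARC by 0.24 ± 0.07), and 1 of 10 genes of Mueller glia and astrocytes rose (CD44, by 0.24 ± 0.07). Another probe of VWF was at 0.03 and another of THBS1 at -0.06. SLC45A2, of the pigment epithelium, rose by 0.25 ± 0.07 and was at least 1.16-fold higher, since its control channel was not well above background, but was at -0.18 under median centring. PTPRC, of immune cells, was higher through a probe at 0.29, with its brightest at 0.07. Of 13 trefoil and secretory epithelial genes, TFF1 rose, and KRT18 was lower through a probe at -0.28, with its brightest probe at 0.20 under median centring. None of these lists passed camera, with adjusted p of 0.60 for endothelial, 0.24 for fibroblast, 0.43 for glial, 0.77 for pigment epithelial, 0.38 for immune and 0.59 for trefoil and secretory genes. Adjusted over the list alone, 2 endothelial, 2 fibroblast, 4 glial, 1 pigment epithelial, 0 immune and 3 trefoil and secretory genes were higher, and 1 endothelial gene was lower.

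The lists not described by their members did not pass camera either. The lowest adjusted p among them was that of cholesterol biosynthesis at 0.072, with a mean of -0.090 over 18 genes and of 0.29 under median centring. Of these genes 1 was called, STARD4, which was higher at 0.30 and is named here after its values were seen. Adjusted over the list alone, 1 was higher and 7 were lower. Housekeeping genes had a mean of 0.12 (adjusted p 0.24), with 4 of 15 higher and 1 lower (5 and 1 adjusted over the list alone). The list of MYC targets and ribosome biogenesis had 1 of 20 higher and 3 lower (3 and 3 adjusted over the list alone; adjusted p 0.80), and interferon response genes had 2 of 14 higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p 0.67). In the lists of G1/S genes, MYC targets, oxidative stress genes and retinoblastoma drivers, camera's direction was down while the list's mean was just above 0, at 0.0030, 0.014, 0.017 and 0.0022. Camera sets the test statistics of a list against those of all other genes, so its direction can differ from the sign of the mean ratio. The median of the Wnt target list was 0.026 while its mean was -0.020. Under fry, 0 lists passed in a common direction and 0 in either direction. The labels call the arrays biological replicates and say no more of how the cultures were kept apart.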

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

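With 1 residual degree of freedom and no array with exchanged dyes, these results were open to the choice of processing; the causes of the shifts were not tested except where the construction of an alternative shows them. Dim probes set a further limit, since 61.8% and 63.7% of probes were well above background in the control channel. Leaving out a replicate leaves a value without a test, so it gave no count of calls and no list test; TFF1 then ranged from 1.25 to 1.99. The counts of called probes and genes stayed within 1.5 times of the reported 2547 and 2395 with no background correction (2188 probes, 2075 shared), the stricter filter (2271, 2233 shared) and the trended and robust fit (2909, 2449 shared). So did the count of probes, the only one computed, with the trend on base composition taken out (2284, 1912 shared; added after the data had been seen). They moved further with no filter on dim probes (1537 probes and 1468 genes, over 34079 probes tested), and with the order of background correction first planned (1539 probes and 1457 genes, 72.6% of the probes higher against 54.2%). The excess of higher calls was lost with the stricter filter, at 48.8% of the probes higher, and with no filter, at 48.5%. That share was 51.4% with no background correction, 51.9% with the trended and robust fit and 51.5% with the base trend taken out. Median centring called 17600 probes and 13730 genes, 71.1% of the probes higher, and moved the median of all probes by 0.19. A minimum log2 ratio of 1 left 1 probe and 1 gene. The processed signals called 0 probes and 0 genes with limma (5309 probes at an unadjusted p under 0.05), and the deposited log2 ratios of the series 0 probes and 0 genes (5294). With the channels as separate samples and no replicate block, which drops the pairing on the array, limma called 0 probes and 0 genes (2108 at an unadjusted p under 0.05). The correlation of the arrays, 0.56 as reported, was 0.59 with no background correction, 0.60 with processed signals, 0.88 with median centring, 0.59 with the value table, 0.51 with no filter, 0.57 with the stricter filter and 0.40 with the planned order.

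TFF1 was positive under every alternative run. It was no longer called with the processed signals (1.90, adjusted p 0.14), the value table (1.90, adjusted p 0.14), the trended and robust fit (1.62, adjusted p 0.070) and without the replicate block (1.62, adjusted p 0.56). Its adjusted p ranged from 6.96e-41 with the planned order, where the ratio was 1.27, to 0.56. The 1 list called in the reported fit became 0 with no background correction, 0 with processed signals and 0 with the value table. It became 0 as well with fry and with a correlation estimated from 1 residual degree of freedom. It became 9 with median centring, all upwards, and 2 with the planned order, where hypoxia and glycolysis was joined by cholesterol biosynthesis downwards (adjusted p 0.0458). With the mean over all probes of a gene 1 list was called, but it was G2/M and mitosis downwards (adjusted p 0.0435) in place of hypoxia.

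Under median centring, which leaves the trend of ratio with brightness in place, a sign can change through brightness alone. Of the 82 genes named by the rule, 27 had a ratio of the other sign there. These were CDKN1A 0.23, MIR17HG 0.033, CRX 0.40, TFF2 -0.17, TFF3 -0.095, PHLDA3 0.16, PLK3 0.16, DIABLO 0.34, BCL2L1 0.083, TRAF2 0.34, TK1 0.36, E2F1 0.16, MCM7 0.60, AURKB 0.11, KIF23 0.20, CDK1 0.22, PLK1 0.28, NCOA3 -0.018, DICER1 0.29, DGCR8 0.26, DROSHA 0.45, KRT18 0.20, PRDM1 0.090, VAMP2 0.0067, SYP 0.061, SLC45A2 -0.18 and GCLM 0.24. With the planned order MIR17HG was at 0.0016 and TFF2 at -0.0081. With the processed signals 60 of the 82 kept their direction and lost their call, as did 60 with the value table, 60 without the replicate block, 27 with no filter, 21 with the planned order, 8 with no background correction, 7 with the trended and robust fit, 7 with median centring and 4 of 77 with the stricter filter.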

Other observations

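The tests on the hypoxia genes against normalization and against chance, both tests on ribosomal protein genes and the removal of the trend on single bases were chosen after the results were seen, as were the genes named in this part. The BMP-responsive genes of the ID family, inhibitors of DNA binding that hold progenitor cells back from differentiation, had opposite ratios in the replicates. ID1 was at 0.84 on array 1 and -1.13 on array 2, ID2 at 0.97 and -0.26, ID3 at 0.86 and -0.28 and ID4 at 0.68 and -0.15. BAMBI, a decoy receptor of the same pathway, was at 0.67 and -0.33, and SMAD7, an inhibitor of it, at 0.15 and -0.32. The mean ratio of the list of TGF-beta and BMP targets differed by -0.54 (array 2 minus array 1), below all of 10000 random lists of the same size matched on brightness (percentile 0). In the control channel the list's mean signal differed by -0.079 between the arrays, and in the TFF1 channel by -0.61. ID1 was the only probe called when the sign of array 2 was turned (limma, adjusted p 0.0169). The TGF-beta and BMP list therefore had a mean near 0 in the comparison of the groups (0.069) through opposite values. Cone photoreceptor genes were higher by 0.17 on array 2 than on array 1 (percentile 99.9), with 11 of 12 genes in that direction, and for p53 targets the difference was -0.17 (percentile 0.01), with 1 of 25 genes higher on array 2. Other lists also lay outside the middle 95% of random lists. Caspases and pro-apoptotic genes differed by -0.092 (percentile 0.39; 8 of 24 genes higher on array 2). Lower on array 2 as well were heat shock genes (percentile 0.11), MAPK and immediate early genes (0.86), synaptic and neuronal genes (1.5), CDK inhibitors and RB family members (1.61) and oxidative stress genes with metallothioneins (1.74). Higher on array 2 were cholesterol biosynthesis (percentile 99.8), rod photoreceptor (98.9) and retinal progenitor genes (98.4). The random lists took their genes independently, and none of these percentiles was adjusted for the number of lists compared. For every list named here, the percentile therefore cannot weigh a chance difference that genes varying together would share. With 1 array per replicate, the spread of such shared differences could not be measured.

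Hypoxia and glycolysis genes also separated the replicates. All 19 measured members had a higher ratio on array 2 than on array 1, with a mean difference of 0.58. PDK1 was at 0.037 and 1.19, HK2 at -0.18 and 0.93, ALDOC at -0.13 and 0.84 and VEGFA at -0.033 and 0.63. Background correction or normalization of one array is argued against by the list's difference of 0.578 with no background correction, 0.639 in the processed signals and 0.616 with median centring in place of loess. Random lists matched on brightness all lay below it (percentile 100), which argues against a draw of unrelated genes. Those lists took their genes independently, and the list was tested after its values were seen. The percentile therefore cannot weigh a chance difference that genes varying together would share. A different state of the control culture of replicate 2 would need a fall in its control channel, where the list's mean signal was higher by 0.169, against 0.76 in the TFF1 channel. What set the TFF1-overexpressing RNA of replicate 2 apart was not tested, and with 1 array per replicate a difference of that culture cannot be parted from a response to TFF1 that varied.

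Ribosomal protein genes stood higher in the TFF1 channel on both arrays: the median over 82 genes was 0.27 (0.25 on array 1 and 0.26 on array 2), with 55 called higher and 0 lower. Their probes are bright, but probes of other genes matched on brightness had a median of 0.13, and the difference of 0.139 (95% bootstrap interval 0.0814 to 0.204) argues against brightness as the whole cause. With median centring, which uses no local fit, the median was 1.03 against 0.85 for the matched probes, a difference of 0.179 (0.111 to 0.232). Loess shifts probes of the same brightness nearly alike, so the match on brightness already takes out most of its effect. The difference under median centring is therefore no separate test of loess. A dye effect common to these probes may still account for the shift, since no array had the dyes exchanged, so whether the transcripts rose with TFF1 stays open.

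The small ratios of one sign on both arrays, which make up nearly all calls, could come from the dyes or from the TFF1 lentivirus. Any other difference between the TFF1 and control cultures that both replicates shared could give them too and was not tested. A dye effect specific to single probes is argued against as the whole cause by genes with another tested probe. Of 1008 other probes, 698 (69.2%, 95% binomial interval 66.3 to 72.1) had the sign of the called probe. Of the 1008, 172 were called the same way and 22 the other way. A gene with several called probes entered more than once, so the pairs are not independent and the interval may be too narrow. The share among genes without a call was not computed. The size was shared less than the sign, since the median was 0.30 in size for the called probes and 0.084 in the called direction for the others, so part of the called ratios may still be specific to the probe. A dye effect that follows base composition is argued against as the whole cause: Spearman's rho with G and C content was -0.0826, within the bound of 0.1 in size set beforehand, although array 1 alone was outside it at -0.103 (array 2 at -0.040). The direction of the calls followed G and C content, with 354 higher and 184 lower in the fifth of probes with the least and 97 higher and 276 lower in the fifth with the most, so a part of the small ratios may come from it. Single bases can cancel in that sum and 3 of them lay outside the bound (T 0.22, G -0.14, A -0.13 and C 0.031), but the trend on single bases held 5.10% and 4.49% of the variance on the arrays. With that trend removed, 2284 probes were called, 1912 of them shared, and the arrays correlated at 0.54 against 0.56. The lentivirus itself could not be tested, since 0 arrays had the overexpressing RNA in Cy3. The effects of TFF1, of the dye and of any other difference between the cultures that both replicates shared cannot be told apart.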
